A study of Mus musculus with 16 samples.

How the data were processed

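RNA of whole mouse epididymides was measured on Affymetrix expression arrays. The epididymis is the coiled duct that carries sperm from the testis, and it grows from the Wolffian duct of the embryo. Per the labels, both epididymides of 1 CD-1 male (an outbred mouse stock) made 1 sample, samples were not pooled, and each animal came from a different dam. There were 3 arrays at each of 5 stages, gestational days 12, 14, 16 and 18 (gd12, gd14, gd16, gd18) and postnatal day 2 (pnd2), which the labels place at Theiler stages 20, 22, 24, 26 and 27. A further array held a pool of 4 male and 4 female whole newborns at postnatal day 0.5, with a different strain label. The organs were excised whole, RNA went through 2 rounds of amplification in the Affymetrix two-cycle protocol, and the product was labelled with biotin.

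The deposited table holds 1 intensity (signal) per probe set and array on a linear scale. Per the submitters' processing notes it came from GCOS, the Affymetrix scanner software. The signal algorithm, the detection calls and the software version are not given in the sources used here. The mean of each column without its lowest and highest 2% of probe sets was between 499.9 and 500 on all 16 arrays, as a scaling of each array by a single factor leaves it. Medians over probe sets ran from 110.3 to 134 on 15 of the 16 arrays and came to 81.24 on pnd2 replicate 3, so no further normalization between arrays was seen. A single scaling factor keeps ratios within an array. A change in many bright transcripts inside the trimmed range shifts all others of that array together.

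The table had 45101 probe sets. Of these, 64 were controls, 34945 were listed with 1 gene symbol, 932 with several and 9160 were not listed. The gene identifiers of 34754 of the single-symbol probe sets were found in the reference gene table (assembly GRCm38.p6), and 0 symbols differed from it. Values were taken as log2(signal + 16). A probe set was kept if it lay at or above its own array's median on at least 3 of the 15 epididymis arrays, which 25981 did, 21613 of them with 1 symbol. Each gene was represented by its brightest kept probe set, which left 12239 genes. Signals well below 16 all map close to the same value, so a fold against such a level depends on that constant. Genomic positions were not used here.

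Stages were compared with limma 3.58.1 in R 4.3.3, as a model with 1 mean per stage fitted to the 15 epididymis arrays and moderated variances with an intensity trend. The 5 comparisons were the 4 consecutive intervals and pnd2 against gd12, with a moderated F test for any change over the 5 stages. Benjamini-Hochberg adjustment was made within each comparison, and a gene is called changed at an adjusted p under 0.05. Log2 changes are given with the standard error (SE) of the fit and n = 3 arrays per stage, and a fold is 2 to the power of the size of the log2 change. No batch is given in the labels, and the arrays carry no pairing between stages. With 3 arrays per group the number of animals sets the precision.

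The genes named are, per comparison, up to 12 with the largest rise and up to 12 with the largest fall. They were taken from called genes whose 3 arrays of one stage all lay above the 3 of the other and whose mean in the higher stage was at or above the middle of the arrays. For a single unchanged gene, such a separation in either direction has a chance of 10%. Genes named only by a clone or model number were passed over. In addition, 29 gene lists were fixed, and members of these lists are named. They cover Wolffian duct and mesonephros regulators, Hox cluster genes, steroid receptors and androgen metabolism, epididymal secreted proteins, luminal ion and water transport, epithelial keratins and junctions, smooth muscle contractile genes and extracellular matrix. They also cover cell division, the Wnt, TGF-beta, FGF and Hedgehog pathways, imprinted growth genes, immediate early and stress genes, histocompatibility and interferon genes, complement and innate defence, ribosomal proteins and oxidative phosphorylation. Markers of other tissues and cells made up the rest, for testis Sertoli and interstitial cells, germ cells, nephron, endothelium, erythroid cells, macrophages, nerve, skeletal muscle, adipocytes and mesothelium.

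Lists were tested with camera, which compares a list with the other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry. Adjustment was over the 29 lists within a comparison. The groups, comparisons, filter, lists, rule for naming genes and most alternatives were fixed before the data were examined. Those alternatives were quantile normalization, median centring, constants of 1 and 64, other filters, other choices of probe set, no trend, array quality weights, stricter calls, fits to the 6 arrays compared, and leaving out each array in turn. The fit without 3 arrays in doubt (pnd2 replicate 3, gd14 replicate 10 and gd16 replicate 9) was chosen after seeing the data. So were lists of adrenal cortex, adrenal chromaffin, Sertoli cell, early gonad and hypoxia-induced genes, which are used only in the closing section. Expression of Xist and 3 Y-linked genes was checked on each array.

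The fit was tested on simulated data with the spread of these arrays, 12239 genes and 200 changed ones. It recovered 42% of 2-fold and 83% of 4-fold changes between gd12 and gd14, with 7 false calls (5.3% of the calls), and 38% and 88% between gd18 and pnd2, with 9 false calls (6.67%). With the spread of the arrays without pnd2 replicate 3, it recovered 67% of 2-fold and 92% of 4-fold changes. The simulated genes varied independently, each with the same spread at every stage. The real spread was unequal. The SD over genes of the log2 difference from the stage mates was 1.176 on pnd2 replicate 3 and 0.357 on gd14 replicate 10. The simulated rates may therefore not hold for the real data, above all at pnd2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.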

Results

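Expression was measured in the epididymis of male mice at 4 fetal stages and shortly after birth, and the question set by the design is how each stage differs from the one before it. There were 3 animals, and so 3 arrays, at each of gd12, gd14, gd16, gd18 and pnd2, and 1 array of pooled whole newborns. Signal gives a relative level of a transcript, so genes are compared between stages and not with each other.

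In a principal component analysis of the 15 epididymis arrays the first component held 38.2% of the variance, the second 25.3% and the third 9.47%. The mean correlation of an array with the others of its stage was 0.959 at gd14, 0.952 to 0.954 at gd16 and gd18, and 0.943 to 0.948 at gd12. At pnd2 it was 0.919 and 0.917 for replicates 1 and 2 and 0.881 for replicate 3. Replicates 1 and 2 correlated with each other at 0.955, and with replicate 3, which lowered their means, at 0.883 and 0.880. On pnd2 replicate 3 the signal at the 3' end of Gapdh was 63.16 times that at the 5' end, against 4.333 to 7.18 on the other 14 epididymis arrays. For Actb the ratio was 80.73, against 2.404 to 4.141. This array also lay at least 2-fold from the mean of its stage mates for 4428 of 12239 genes (36.2%), against 13% and 13.7% for the other pnd2 arrays, whose reference includes it, and 2.22% to 6.11% for the fetal arrays. All stages share 1 estimate of the spread, so each count of changed genes is followed by the count without this array.

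**Figure D1:**
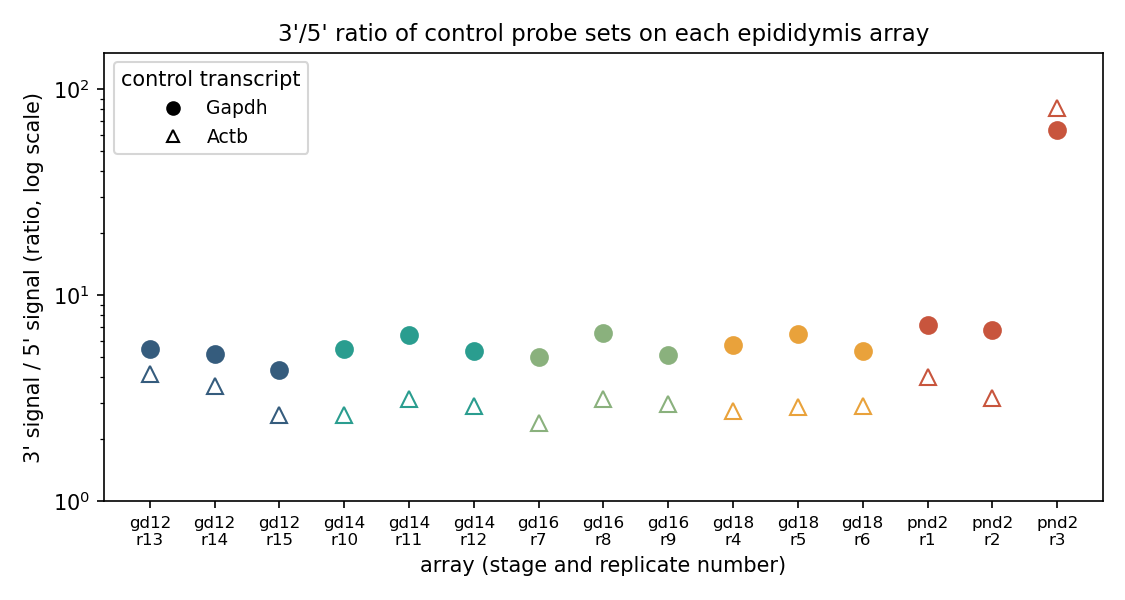
Ratio of the 3' to the 5' signal (log scale) of the Gapdh (filled circles) and Actb (open triangles) control probe sets on each of the 15 epididymis arrays, coloured by stage. On pnd2 replicate 3 the ratios were 63.16 and 80.73, and on the other 14 arrays they ran from 4.333 to 7.18 for Gapdh and from 2.404 to 4.141 for Actb.

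**Figure D2:**
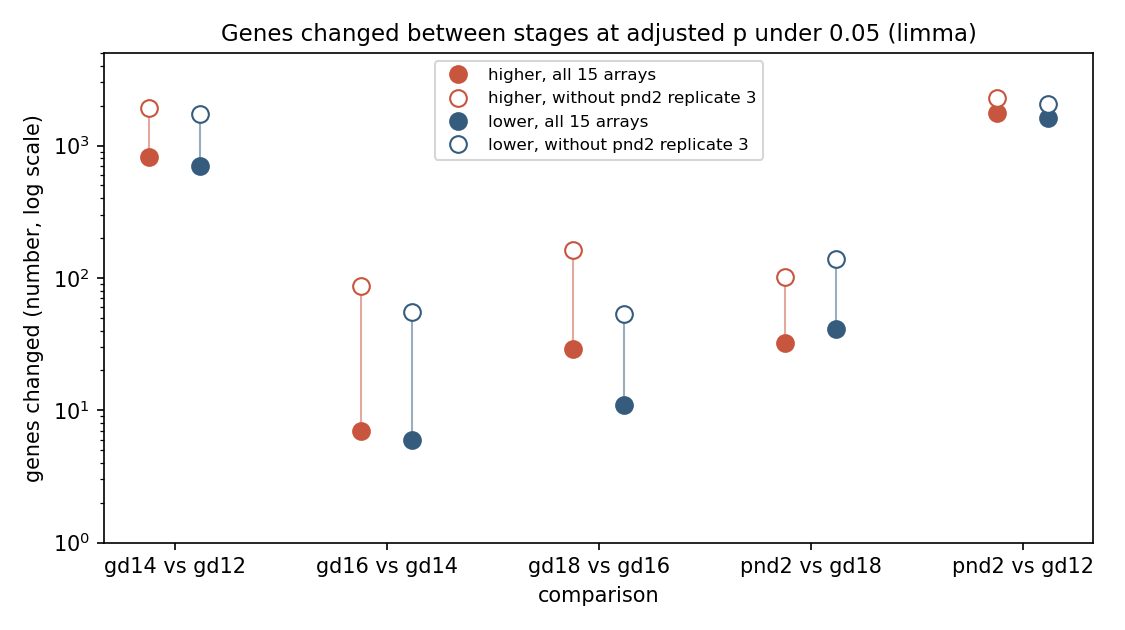
Number of genes called higher (red) and lower (blue) in each comparison (log scale), with all 15 arrays (filled) and without pnd2 replicate 3 (open). The interval from gd12 to gd14 had 1524 changed genes, and the 3 later intervals had 13, 40 and 73.

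Between gd12 and gd14 genes of the extracellular matrix and of macrophages rose, and genes of germ cells and of cell division fell. Gonad tissue in the gd12 samples could be a source of the falling germ cell and gonad genes, which the closing section takes up. Ogn (osteoglycin, a small matrix proteoglycan) was 27.3-fold higher at gd14 (log2 change 4.77 ± 0.37, SE, n = 3 per stage, adjusted p = 2.8e-06). Cldn1, a tight junction protein, was 18.1-fold higher (4.18 ± 0.24), and Esr1, the estrogen receptor alpha, was 11.1-fold higher (3.48 ± 0.31, adjusted p = 9.84e-06). Kctd14 was 42.3-fold lower (-5.40 ± 0.28, adjusted p = 1.22e-07), and Dppa5a, expressed in pluripotent and germ cells, was 25.5-fold lower (-4.67 ± 0.28). In all, 1524 of 12239 genes changed, 821 higher and 703 lower at gd14, and 931 of them by at least 2-fold. Without pnd2 replicate 3 there were 3648, which include all 1524, with 1919 higher and 1729 lower, and without the 3 arrays in doubt there were 2776 (1429 higher, 1347 lower). After median centring 651 were higher and 695 lower, so the larger direction depends on the scaling.

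Other genes with the largest rises to gd14 were Nfix, a nuclear factor I transcription factor, at 26.7-fold, Penk (proenkephalin) at 15.6-fold, the collagen Col12a1 at 14.9-fold and Adgrg2, an adhesion receptor of the efferent duct and epididymal epithelium, at 13.9-fold. Chodl, Col8a1, Cyp7b1, an oxysterol hydroxylase, Lum (lumican) and Moxd1 followed, at 12.7-, 11.9-, 9.41-, 8.41- and 8.36-fold. Genes with the largest falls were the embryonic beta globin Hbb-bh1 at 46.3-fold, Tesc at 42.5-fold, the homeobox genes Rhox6 and Rhox9 at 33.5- and 25.3-fold, and Cbln4 at 26.2-fold. Sall4, Zfp42 and Sox2, transcription factors of pluripotent cells, were 21.1-, 18.8- and 17.1-fold lower. Lhx9, a homeobox gene needed for the gonad, was 18-fold lower, and Cpa1, a carboxypeptidase, was 19.4-fold lower. The SE of these log2 changes lay between 0.25 and 0.65, and each of the 24 genes kept its call with any array left out. At gd12 the SD on the log2 scale was 1.89 for Adgrg2 and 1.39 for Nfix, so the size of their folds depends on single gd12 arrays.

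Of 37 measured genes of the extracellular matrix, 27 rose from gd12 to gd14 and 0 fell, and 28 rose when adjusted over the list alone (camera adjusted p = 4.71e-26). They included Aspn at 9.35-fold, the collagen VI chains Col6a1 and Col6a2 at 8.30- and 5.73-fold, Dcn (decorin) at 8.10-fold and Lox, which crosslinks collagen, at 5.45-fold. Of 21 macrophage and leukocyte markers, 14 rose and 0 fell, and 18 rose adjusted over the list alone (camera adjusted p = 9.7e-12). F13a1, Mrc1 and Csf1r, the receptor for colony stimulating factor 1, were 4.92-, 4.69- and 2.81-fold higher. Of 30 Wnt pathway genes, 10 rose and 1 fell (15 and 2 adjusted over the list alone, camera adjusted p = 2.88e-06). Apcdd1 and Wif1, which restrain Wnt signals, and Rspo3, which enhances them, were 6.37-, 5.73- and 5.39-fold higher, and Lgr5 was 1.94-fold lower. In the TGF-beta, BMP and activin list of 30, 7 rose and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.000481). Inhba, which encodes the subunit of activin A, was 8.23-fold higher (3.04 ± 0.46), Inhbb was 16.1-fold lower (-4.01 ± 0.32), and Amhr2, the receptor for anti-Müllerian hormone, was 3.08-fold lower. Of 11 complement and innate defence genes 5 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 2.94e-05). Of 16 imprinted growth genes 5 rose and 0 fell, both over all genes and adjusted over the list alone (camera adjusted p = 7.7e-05), with Dlk1 at 6.07-fold and Meg3 at 2.75-fold.

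Of 47 cell division genes, 24 fell from gd12 to gd14 and 1, Ccnd2, rose (29 and 2 adjusted over the list alone, camera adjusted p = 2.2e-12). Mybl2, Mcm2 and Cdc20 were 2.29-, 1.92- and 1.84-fold lower. Of 10 germ cell markers 7 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 3.75e-09), among them Dazl and Ddx4, RNA-binding proteins of germ cells, at 8.78- and 5.33-fold, and Pou5f1 at 5.29-fold. These 8 lists, from the matrix to the germ cell markers, also passed with an estimated correlation, at adjusted p between 0.00188 and 0.0322. Of 13 testis Sertoli and interstitial markers 8 fell and 0 rose (9 and 0 adjusted over the list alone, camera adjusted p = 4.61e-06, adjusted p = 0.0938 with an estimated correlation). Dhh, Nr5a1, Gata4, Dmrt1 and Sox9, which act in the supporting cells of the gonad, were 10.1-, 9.34-, 7.16-, 7.13- and 3.19-fold lower.

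**Figure D3:**
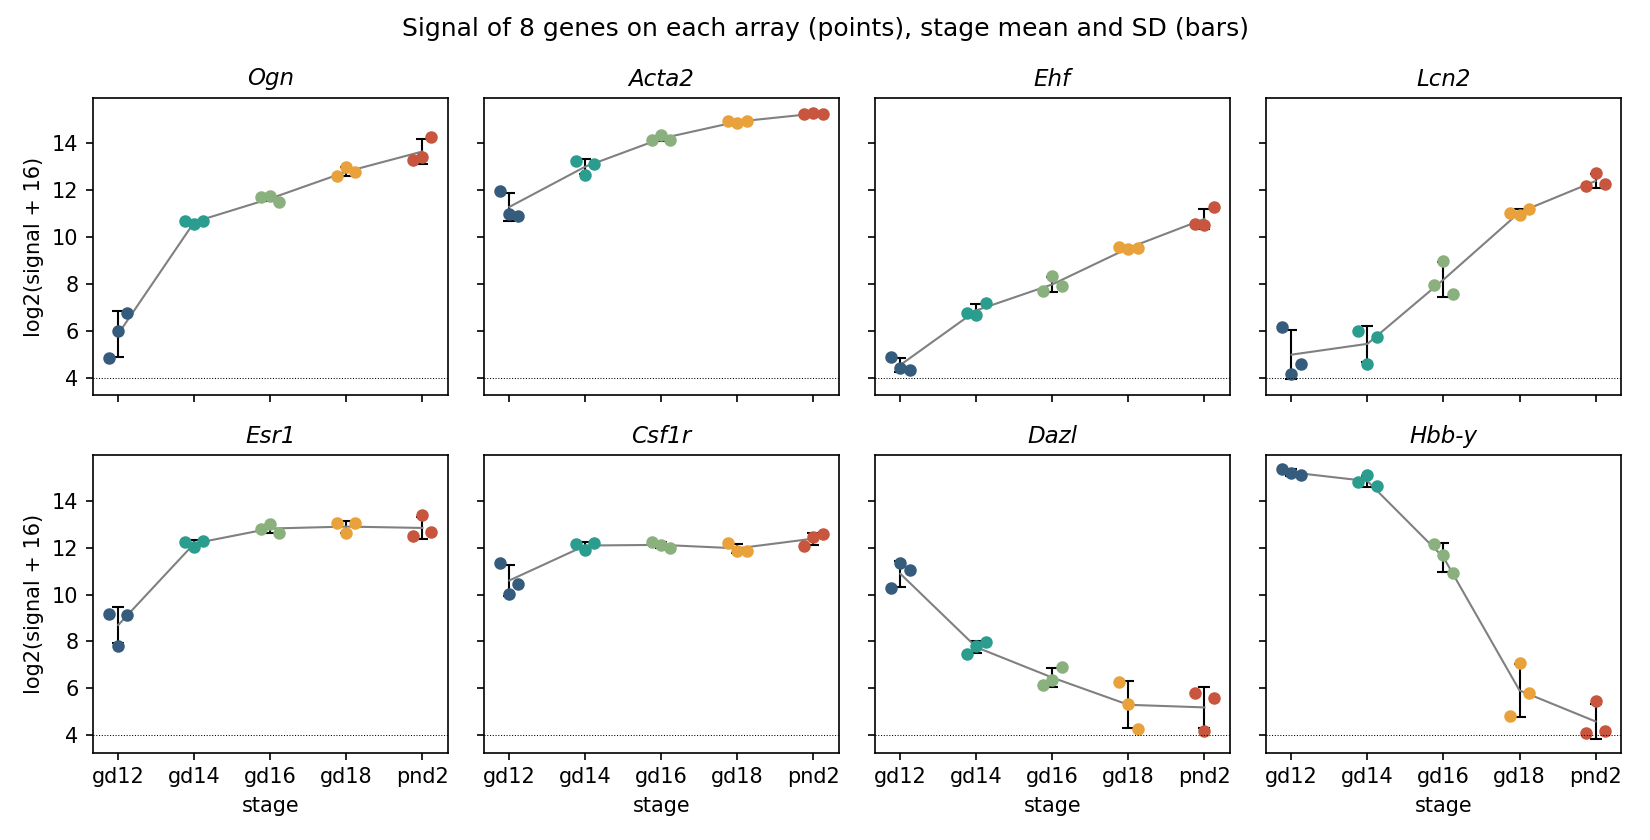
Signal on the log2(signal + 16) scale of 8 genes on each epididymis array (points, 3 per stage), with the stage mean (line) and SD (bars). Ogn, Acta2 and Ehf were higher at pnd2 than at gd12 by 220-, 15.7- and 75.1-fold, Dazl was lower by 52-fold, and the dotted line marks a signal of 0.

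Further lists passed with the preset correlation between gd12 and gd14 and not with an estimated one. Of 30 genes of epithelial keratins and junctions 7 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.000353, adjusted p = 0.173 with an estimated correlation). Krt18, Krt19 and Krt8, keratins of simple epithelia, were 3.21-, 3.17- and 2.64-fold higher, Ehf, an epithelial transcription factor, was 5.02-fold higher, and the splicing regulator Esrp1 was 2.86-fold lower. Of 18 smooth muscle genes 6 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 6.68e-05, adjusted p = 0.0615 with an estimated correlation), among them Tagln at 5.61-fold and Acta2, smooth muscle actin, at 3.30-fold. In the FGF, EGF and IGF list 9 of 27 rose and 2, Etv5 and Fgf9, fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.000287, adjusted p = 0.0526 with an estimated correlation). Of 41 oxidative phosphorylation genes 5 fell and 0 rose, Cycs (cytochrome c) by 1.80-fold (camera adjusted p = 6.24e-05, adjusted p = 0.0836 with an estimated correlation). Of 9 erythroid genes Hbb-bh1 and Hba-x, embryonic globins, fell and Hbb-b2, an adult globin, rose by 4.40-fold (camera adjusted p = 0.0329, adjusted p = 0.172 with an estimated correlation). Hox cluster genes (5 of 19 higher), mesothelium markers (4 of 14 higher, 1 lower) and the Hedgehog list (4 of 11 higher, with Shh at 3.27-fold, and Dhh lower) had camera adjusted p = 0.0151, 0.0219 and 0.0329, and adjusted p = 0.433, 0.203 and 0.0836 with an estimated correlation. The gd12 arrays differ in Hox genes, with Hoxa9, Hoxc10, Hoxa10 and Hoxd13 at signals of 7376, 1198, 955.9 and 458.6 on replicate 13, against 1086 and 2043, 178.2 and 184, 64.9 and 195.5, and 40.13 and 26 on replicates 14 and 15. Without gd12 replicate 13 the Hox list had camera adjusted p = 3.48e-05, and without replicate 14 it did not pass (0.0771). Among 15 steroid receptor and androgen genes 3 rose and 2 fell, and the list did not pass (camera adjusted p = 0.62). Besides Esr1, Nr3c1, the glucocorticoid receptor, was 3.13-fold higher, and Hsd11b2, which inactivates glucocorticoids, was 2.53-fold lower. The count of changed genes fell to 938 without gd12 replicate 14 and to 980, 981 and 994 without gd14 replicates 11, 10 and 12. With pnd2 replicate 3 left out, the erythroid list no longer passed (camera adjusted p = 0.0593), and without the 3 arrays in doubt neither did the Hox, Hedgehog and erythroid lists (0.055, 0.0547 and 0.0556).

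From gd14 to gd16 few single genes passed, and matrix and smooth muscle genes rose as lists. Aspn (asporin, a matrix proteoglycan) was 3.48-fold higher at gd16 (1.80 ± 0.22, SE, n = 3 per stage, adjusted p = 0.00357). Eln (elastin) was 2.51-fold higher (1.33 ± 0.23), Smoc2 was 2.29-fold higher and Lama2, a laminin chain, was 2.18-fold higher (1.13 ± 0.19). Irs4, an insulin receptor substrate, was 4.70-fold higher (2.23 ± 0.35, adjusted p = 0.0252), and Fbxo32, a ubiquitin ligase subunit, and Maob (monoamine oxidase B) were 3.25- and 2.54-fold higher. The embryonic globin Hbb-y was 9.54-fold lower (-3.25 ± 0.48, adjusted p = 0.0174), the chromatin protein gene Hmga2 was 2.81-fold lower (-1.49 ± 0.21, adjusted p = 0.017), and the germ cell gene Dppa5a was 4.92-fold lower.

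In all, 13 genes changed in this interval, 7 higher and 6 lower, while 731 had an unadjusted p under 0.05. Leaving out pnd2 replicate 3 gave 142, 87 higher and 55 lower, and these include the 13. Of 37 matrix genes 3 rose and 0 fell, and 14 rose when adjusted over the list alone (camera adjusted p = 5.53e-22). Of 18 smooth muscle genes 0 passed over all genes and 8 were higher adjusted over the list alone (median log2 change 0.83, camera adjusted p = 3.92e-13). Both lists passed with an estimated correlation (adjusted p = 0.00379 and 0.00924). Of 10 germ cell markers 1 fell, and 3 were lower adjusted over the list alone (median log2 change -1.13, camera adjusted p = 1.86e-05, adjusted p = 0.051 with an estimated correlation). Oxidative phosphorylation, testis and ribosomal protein lists had lower medians (-0.17, -0.74 and -0.12) and camera adjusted p = 0.000375, 0.0071 and 0.0155, and adjusted p = 0.32, 0.457 and 0.453 with an estimated correlation. Mesothelium and Hox lists had higher medians (0.25 and 0.22) with camera adjusted p = 0.0154 and 0.0192, and adjusted p = 0.406 and 0.581 with an estimated correlation.

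The count for gd16 against gd14 depended on single arrays. It fell to 3 without gd14 replicate 10 or 11, to 4 without gd14 replicate 12 or gd16 replicate 8, to 5 without gd16 replicate 7 or 9 and to 7 without gd18 replicate 5, and it rose to 32 without gd12 replicate 13. With a constant of 1 in place of 16 the calls of Hbb-y, Eln and Lama2 were lost (adjusted p = 0.225, 0.0554 and 0.0554), after median centring those of Irs4 and Lama2 (0.0749 and 0.103), and with the mean of all probe sets of a gene those of Fbxo32 and Eln (0.234 and 0.0795). Aspn and Fbxo32 were called with any array left out, and 7 of the 9 genes named by the rule were not called in some of these fits. On gd16 replicate 9 the testis markers lay above the other gd16 arrays (median log2 deviation 0.82, 12 of 13 genes higher), with Cyp17a1, a steroid-making enzyme, at a signal of 2211 against 23.34 and 8.5. On gd14 replicate 10 Cyp17a1 was at 949.2 against 301.7 and 218.2. With these 2 arrays and pnd2 replicate 3 left out, 33 genes changed, 27 higher and 6 lower, and the mesothelium and ribosomal protein lists no longer passed (camera adjusted p = 0.0587 and 0.151).

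From gd16 to gd18 few single genes passed, and as lists secreted protein, innate defence, histocompatibility and matrix genes rose and erythroid genes fell. Lcn2, a lipocalin that binds bacterial siderophores, was 7.32-fold higher at gd18 (2.87 ± 0.49, SE, n = 3 per stage, adjusted p = 0.0257), and Defb29, a beta-defensin, was 7.07-fold higher (2.82 ± 0.53). Cp (ceruloplasmin, a copper carrier) was 5.10-fold higher and Socs2, a suppressor of cytokine signals, was 4.85-fold higher (2.28 ± 0.28, adjusted p = 0.0021). Maob was 4.27-fold higher (2.09 ± 0.22, adjusted p = 0.000711). Hbb-y was 51.2-fold lower (-5.68 ± 0.48, adjusted p = 0.000118), and Hmga2 was 3.57-fold lower (-1.84 ± 0.21, adjusted p = 0.0015).

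In all, 40 genes changed, 29 higher and 11 lower at gd18, 37 of them by at least 2-fold. With pnd2 replicate 3 omitted there were 214, 161 higher and 53 lower, and these include the 40. Adm (adrenomedullin), B4galnt2, Crip1, Aspn, Smim22, Ehf and Cdcp1 were 7.15-, 4.23-, 3.52-, 3.14-, 3.00-, 2.92- and 2.84-fold higher. Amhr2, Chrna7, a nicotinic receptor subunit, Ndnf, Tenm4 and Cdh2 (N-cadherin) were 4.19-, 3.25-, 2.30-, 2.12- and 2.01-fold lower. The calls of Adm, Amhr2 and Hbb-y each rest on a probe set that can bind related sequences. With such probe sets avoided the log2 change was 1.20 for Adm (adjusted p = 0.678), -0.65 for Amhr2 (adjusted p = 0.999) and -2.09 for Hbb-y (adjusted p = 0.266). In that fit Defb29, Cp and Cdh2 kept their probe sets and their log2 changes (2.82, 2.35 and -1.01). Their adjusted p went just over the limit (0.0552, 0.0598 and 0.0607).

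Of 37 matrix genes 2 rose from gd16 to gd18 and 0 fell, and 11 were higher adjusted over the list alone (camera adjusted p = 1.43e-13). Mfap5, of elastic microfibrils, was 3.70-fold higher. Of 13 epididymal secreted protein genes 1, Lcn2, rose (3 adjusted over the list alone, camera adjusted p = 0.000327). Of 11 complement and innate defence genes Lcn2 and Cp rose (4 adjusted over the list alone, camera adjusted p = 2.81e-05). Of 11 histocompatibility and interferon genes 0 passed over all genes and 3 were higher adjusted over the list alone (median log2 change 0.70, camera adjusted p = 8.63e-05). Of 9 erythroid markers Hbb-y and Slc4a1, the red cell anion exchanger, fell, the latter by 5.53-fold (camera adjusted p = 1.91e-06). These 5 lists also passed with an estimated correlation (adjusted p = 0.011 for each).

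Of 30 epithelial genes Ehf and the adhesion molecule Epcam rose (5 adjusted over the list alone, camera adjusted p = 2.49e-07, adjusted p = 0.0749 with an estimated correlation). Smooth muscle genes had a median log2 change of 0.47, with 0 of 18 called over all genes and 4 adjusted over the list alone (camera adjusted p = 5.64e-05, adjusted p = 0.0749 with an estimated correlation). Ribosomal protein, stress and adipocyte lists had 0 called members, medians of 0.18, 0.22 and 0.55 and camera adjusted p = 0.000979, 0.00473 and 0.00818, and adjusted p = 0.173, 0.0749 and 0.128 with an estimated correlation. In the Wnt list Wif1 fell by 4.56-fold (camera adjusted p = 0.0227, adjusted p = 0.205 with an estimated correlation). With a constant of 1 in place of 16 the calls of Lcn2, Defb29, Cp, Ehf and Cdh2 were lost (adjusted p = 0.258, 0.252, 0.252, 0.143 and 0.0608), after median centring those of Defb29, Cp, Ehf and Ndnf (0.0552, 0.0552, 0.0668 and 0.0925), and with the mean of all probe sets of a gene those of B4galnt2, Amhr2, Tenm4 and Cdh2 (0.242, 0.0773, 0.0791 and 0.0582). The count of 40 fell to between 6 and 23 when any single array of gd14, gd16 or gd18 was left out, with the lowest value, 6, without gd18 replicate 6. Of the 19 genes named by the rule, Adm, Aspn, Hbb-y, Hmga2, Maob and Socs2 were called with any array left out. Without the 3 arrays in doubt 48 genes changed, 38 higher and 10 lower, and the Wnt list no longer passed (camera adjusted p = 0.0715). Without pnd2 replicate 3 alone the TGF-beta and oxidative phosphorylation lists passed (0.0388 for each). On gd18 replicate 4 testis markers lay above the other gd18 arrays (median log2 deviation 0.65, 12 of 13 higher). Germ cell markers had a median deviation of 0.84 there (6 of 10 higher). This array was not among the 3 in doubt.

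From gd18 to pnd2, across birth, single genes rose and fell, and 0 of the 29 lists passed with both correlations of the camera test, against 8 with the preset one. Spink12, a Kazal-type protease inhibitor gene, was 9.45-fold higher at pnd2 (3.24 ± 0.52, SE, n = 3 per stage, adjusted p = 0.0131), Pzp, a broad protease inhibitor, was 6.96-fold higher (2.80 ± 0.40), and Defb29 was 5.92-fold higher. Ldha (lactate dehydrogenase A) was 3.08-fold lower (-1.62 ± 0.28, adjusted p = 0.0229), Slc2a1, a glucose transporter, was 2.21-fold lower (-1.14 ± 0.21), and Hmga2 was 2.26-fold lower. Alas2, the first enzyme of heme synthesis in red cells, was 9.74-fold lower (-3.28 ± 0.69, adjusted p = 0.0481). The pnd2 SD of Alas2 was 1.66, and its call was lost in 11 of 15 fits with 1 array left out. In all, 73 genes changed, 32 higher and 41 lower, while 2310 had an unadjusted p under 0.05. Without pnd2 replicate 3 there were 240, 102 higher and 138 lower, 72 of them shared with the 73. A limma fit to the gd18 and pnd2 arrays alone called 0 genes, with 950 at an unadjusted p under 0.05. The SEs given here pool the spread of all stages, while the SD of Ldha was 0.80 at pnd2 and 0.01 at gd18.

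Among the other genes with the largest rises at pnd2 were the receptor gene Npy6r, Ccn3, the BMP antagonist Chrdl1, Mt2 (metallothionein 2), Rgn and Nr1d2, a nuclear receptor of the circadian clock, at 6.66-, 5.18-, 3.80-, 3.63-, 3.43- and 3.33-fold. Spin2c was 3.11-fold higher (1.64 ± 0.17, adjusted p = 0.00132), Mfap5 2.91-fold and Angptl4, an inhibitor of lipoprotein lipase, 2.88-fold. Among the largest falls were Acer2 (alkaline ceramidase 2), P4ha1, a collagen prolyl hydroxylase, Ppp1r3c, which directs a phosphatase to glycogen, Col8a1 and Ak4 (adenylate kinase 4), at 4.47-, 3.81-, 3.39-, 3.00- and 2.47-fold. Nfatc4, Msl1 and Shc1 were 2.43-, 2.32- and 2.17-fold lower. The log2 change of P4ha1 was -1.31 (adjusted p = 0.00797) and that of Ldha -1.19 (adjusted p = 0.00551) without pnd2 replicate 3. Spink12 had a pnd2 SD of 1.04, and without that array its pnd2 level over the newborn pool went from 21.8- to 14.5-fold, so its rise rests partly on that array.

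Of 41 oxidative phosphorylation genes 1, Cycs, rose at pnd2, by 1.88-fold, and 9 were higher adjusted over the list alone (median log2 change 0.41, camera adjusted p = 3.13e-07, adjusted p = 0.126 with an estimated correlation). Of 16 imprinted growth genes 0 passed over all genes and 4 were lower adjusted over the list alone (median -0.65, camera adjusted p = 0.00149, adjusted p = 0.126 with an estimated correlation). Of 19 endothelium markers Flt1, a VEGF receptor, and Icam2 fell, by 3.23-fold (-1.69 ± 0.19, adjusted p = 0.0025) and 3.04-fold (camera adjusted p = 0.00111, adjusted p = 0.267 with an estimated correlation). Of 9 erythroid markers Alas2 fell (camera adjusted p = 0.0272, adjusted p = 0.267 with an estimated correlation). Of 30 epithelial genes Trp63, of basal epithelial cells, rose by 3.73-fold (camera adjusted p = 0.0333, adjusted p = 0.563 with an estimated correlation). Stress, mesothelium and ribosomal protein lists had medians of -0.39, -0.45 and 0.22 and camera adjusted p = 0.0345, 0.0345 and 0.0272, and adjusted p = 0.267, 0.384 and 0.402 with an estimated correlation, and of their members 1, the mesothelium marker Lrrn4, fell. Outside the lists that passed, Synpo2 of the smooth muscle list rose by 2.88-fold and Cdon of the Hedgehog list fell by 1.87-fold. Skeletal muscle markers lay above the other pnd2 arrays on pnd2 replicate 2 (median log2 deviation 3.57, 10 of 10 genes higher), with Acta1 at a signal of 1991 against 34.21 and 4.49. That list had a median of 0.60 and did not pass (camera adjusted p = 0.15).

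The pnd2 arrays differ in scale, and this bears on the directions in this interval. The median log2 change of all genes was -0.05 with the deposited scaling, 0.03 after quantile normalization and 0.19 after median centring, and the share of changed genes that were higher went from 43.8% to 54.9% (62 higher, 51 lower) and 75% (33 higher, 11 lower). Relative to the median of all genes, the oxidative phosphorylation, imprinted and endothelium lists had medians of 0.46, -0.60 and -0.48. After median centring the falls of Slc2a1, Hmga2, Ak4, Nfatc4, Shc1 and Alas2 no longer passed (adjusted p = 0.0996, 0.08, 0.101, 0.0565, 0.0551 and 0.0525), while their log2 changes stayed negative (-0.90, -0.93, -1.06, -1.03, -0.87 and -3.04, against -1.14, -1.17, -1.30, -1.28, -1.12 and -3.28). With a constant of 1 the calls of Pzp, Defb29, Chrdl1, Mfap5, P4ha1, Nfatc4 and Alas2 were lost (adjusted p = 0.0695, 0.162, 0.0567, 0.0518, 0.0537, 0.0539 and 0.0696), with the mean of all probe sets of a gene those of Msl1, Shc1 and Alas2 (0.137, 0.0608 and 0.0512), and after quantile normalization or with other probe sets that of Ak4 (0.0723 and 0.0532). Leaving out gd18 replicate 6, 4 or 5 cut the count from 73 to 3, 13 or 23, and single arrays of gd14 and gd16 other than gd14 replicate 11 brought it to between 37 and 47. Without pnd2 replicate 1 or 2 it was 214 or 184. Spin2c alone of the 24 genes named by the rule was called with any array left out. Without pnd2 replicate 3, smooth muscle, skeletal muscle and histocompatibility lists passed (camera adjusted p = 0.0142, 0.00487 and 0.0452), and stress, mesothelium and ribosomal protein lists did not (0.0653, 0.0653 and 0.0567). Without the 3 arrays in doubt 105 genes changed, 47 higher and 58 lower.

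Over the whole series, from gd12 to pnd2, genes of the matrix, smooth muscle and innate defence rose, and germ cell, erythroid and cell division genes fell. Here too, gonad tissue in the gd12 samples could be a source of the falling germ cell and gonad genes. Ogn was 220-fold higher at pnd2 (7.78 ± 0.37, SE, n = 3 per stage, adjusted p = 4.32e-09), with signals from 12.57 to 94.07 at gd12. Lcn2 was 170-fold higher (7.41 ± 0.49), Ehf was 75.1-fold higher (6.23 ± 0.27, adjusted p = 1.71e-09) and Shh (sonic hedgehog) was 32.5-fold higher (5.02 ± 0.38). Dazl was 52-fold lower (-5.70 ± 0.51), and Amhr2 was 57.4-fold lower (-5.84 ± 0.34, adjusted p = 3.25e-08). In all, 3362 genes changed, 1762 higher and 1600 lower, 2025 of them by at least 2-fold. Without pnd2 replicate 3 there were 4365, 2289 higher and 2076 lower, 3023 of them shared. The split between directions depends on the processing, with 1982 higher and 1159 lower after median centring, 1574 and 1759 with the mean of the probe sets of a gene, and 1894 and 2052 without pnd2 replicate 1 or 1836 and 2047 without replicate 2.

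Other genes with the largest rises from gd12 to pnd2 were Dpt (dermatopontin), Aspn, Nfix, Defb29, Adgrg2, Ecrg4, Penk, Irs4 and Cp, at 169-, 126-, 116-, 108-, 96.9-, 75.3-, 50.1-, 40.3- and 39.9-fold. The gd12 SD was 1.890 for Adgrg2, 1.388 for Nfix and 1.215 for Penk on the log2 scale, so the size of these folds depends on single gd12 arrays. The largest fall was that of Hbb-y, with a log2 change of -10.63 ± 0.48. Its signal went from between 3.5e+04 and 4.21e+04 at gd12 to between 1.32 and 27.9 at pnd2, near or below the added constant, so its fold of 1.58e+03 depends on that constant. Hbb-bh1, Hba-x, Rhox5, Dppa5a, Akr1cl and Dppa4 were 213-, 127-, 112-, 104-, 81- and 69.7-fold lower, and Col9a3, Sox2 and Rpl39l were 61.4-, 51.7- and 50.2-fold lower. All 24 genes named by the rule kept their call with any array left out.

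Of 37 matrix genes 32 rose from gd12 to pnd2 and 0 fell (34 and 1 adjusted over the list alone, camera adjusted p = 4.73e-30). Mgp (matrix Gla protein), Lama2 and Lox were 32.2-, 22.3- and 21.6-fold higher. Of 18 smooth muscle genes 13 rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 4.47e-10), with Pdlim3, Myh11, smooth muscle myosin, and Acta2 at 27.6-, 16.1- and 15.7-fold. Of 11 complement and innate defence genes 9 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 5.39e-07). All 10 germ cell markers fell, over all genes and adjusted over the list alone (camera adjusted p = 1.7e-09), with Ddx4 at 34.6-fold and Mael at 15.5-fold. Of 47 cell division genes 25 fell and 0 rose (25 and 1 adjusted over the list alone, camera adjusted p = 5.39e-07), among them Plk1 and Aurka, mitotic kinases, at 4.03- and 3.79-fold. Of 9 erythroid markers 6 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 1.82e-05). These 6 lists also passed with an estimated correlation (adjusted p from 0.00103 to 0.0308).

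Of 30 epithelial genes 17 rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 1.55e-08, adjusted p = 0.0586 with an estimated correlation), among them Cldn8, Krt8 and Ocln at 23-, 4.39- and 4.08-fold. Of 13 testis markers 8 fell and 0 rose (9 and 0 adjusted over the list alone, camera adjusted p = 6.46e-07, adjusted p = 0.0983 with an estimated correlation), with Cst9, Dmrt1 and Nr5a1 at 49-, 22.7- and 20.8-fold. Of 21 macrophage markers 13 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 1.91e-06, adjusted p = 0.121 with an estimated correlation). Of 13 epididymal secreted protein genes 5 rose and 0 fell, Lcn2, Defb1, Clu (clusterin), Cd9 and Wfdc2 (6 and 0 adjusted over the list alone, camera adjusted p = 0.0276, adjusted p = 0.0841 with an estimated correlation). Of 19 endothelium markers 6 fell and 1, Eng, rose (camera adjusted p = 0.0289, adjusted p = 0.332 with an estimated correlation). Hox (7 of 19 higher), Wnt (13 of 30 higher, 3 lower) and FGF, EGF and IGF genes (11 of 27 higher, 6 lower) had camera adjusted p = 0.0131, 0.022 and 0.0348, and adjusted p = 0.369, 0.171 and 0.229 with an estimated correlation, and without gd12 replicate 14 the Hox list did not pass (camera adjusted p = 0.0569). In the last list Hgf (hepatocyte growth factor) was 10.2-fold lower and its receptor gene Met was 9.85-fold higher. Hedgehog (4 of 11 higher, 1 lower), ribosomal protein (3 of 22 higher) and histocompatibility and interferon genes (4 of 11 higher) had camera adjusted p = 0.0348, 0.0348 and 0.0435, and adjusted p = 0.0983, 0.357 and 0.125 with an estimated correlation.

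Other lists did not pass between gd12 and pnd2. Of 16 Wolffian duct and mesonephros regulators 6 rose and 5 fell (camera adjusted p = 0.769). Gata3, Tfap2a and Lhx1 were 4.74-, 4.52- and 3.07-fold higher, and Eya1, Sall1 and Gdnf, the ligand of Ret, were 5.99-, 4.18- and 3.55-fold lower. Of 15 steroid receptor and androgen genes 5 rose and 3 fell (camera adjusted p = 0.397), with Esr1, Pgr, the progesterone receptor, and Nr3c1 at 17.6-, 5.57- and 4.10-fold higher. Pax2 is not named by the annotation used here and was not analysed here. Of 18 ion and water transport genes 2 rose and 3 fell (camera adjusted p = 0.835). Slc26a3, a chloride and bicarbonate exchanger, was 10.6-fold higher and Aqp5, a water channel, was 12.5-fold lower. TGF-beta, BMP and activin genes (8 of 30 higher, 7 lower), stress genes (4 of 20 higher, 3 lower), imprinted genes (5 of 16 higher, 2 lower) and oxidative phosphorylation genes (3 of 41 higher, 3 lower) had camera adjusted p = 0.397, 0.479, 0.308 and 0.739. Mesothelium, nerve, skeletal muscle, adipocyte and nephron lists did not pass either (camera adjusted p = 0.0883, 0.321, 0.321, 0.511 and 0.337), and of the 10 nephron markers 1 was higher and 2 were lower. When pnd2 replicate 3 was left out the secreted protein, endothelium and ribosomal protein lists no longer passed (camera adjusted p = 0.0828, 0.0556 and 0.11), and the mesothelium list passed (0.029). Without the 3 arrays in doubt 4081 genes changed, 2150 higher and 1931 lower.

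**Figure D4:**
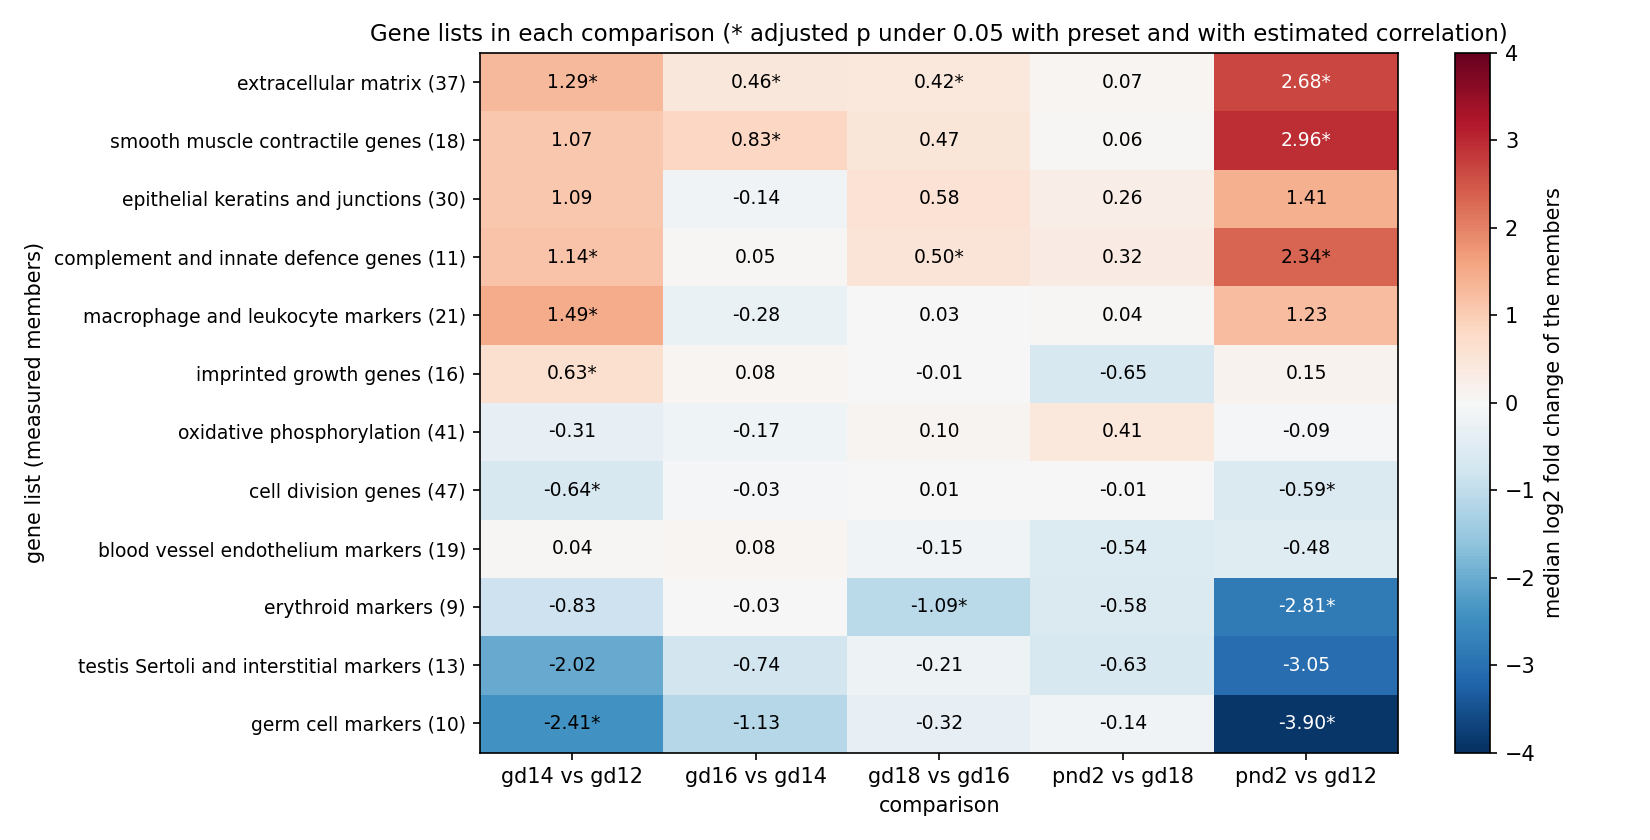
Median log2 fold change of the measured members (number in brackets) of 12 gene lists in the 5 comparisons, coloured from blue (lower) to red (higher in the later stage). An asterisk marks an adjusted p under 0.05 with both the preset and an estimated correlation, and the matrix list had medians of 1.29, 0.46, 0.42 and 0.07 in consecutive intervals.

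Across the 5 stages together 3239 of 12239 genes changed by the moderated F test. There were 5588 without pnd2 replicate 3, and without the 3 arrays in doubt 4768. Over the 5 comparisons 61 of 145 list tests passed with the preset correlation and 21 of these with an estimated one. With any single array left out these 21 kept their call at the preset correlation, and over the 15 such fits 44 calls of the others were lost. The estimated correlation was not rerun in these fits. A list's median, mean and test differed in sign in 13 of the 145, and 0 of these 13 passed. For the genes named by the rule, 52 further probe sets of the same gene were called the same way, 41 were not called and 0 were called the opposite way.

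Log2 changes in intervals that share no arrays were nearly unrelated across genes, which are not independent replicates. Pearson's r was 0.02 between gd14 against gd12 and gd18 against gd16, -0.09 between gd14 against gd12 and pnd2 against gd18, and -0.06 between gd16 against gd14 and pnd2 against gd18. Spearman's rho was -0.01, -0.12 and -0.09. Of genes higher at gd14 than at gd12, 9 were also higher at gd18 than at gd16, where independent lists would share 1.95, and 1 was lower in both (0.632), 2 were higher and then lower (0.738) and 2 lower and then higher (1.67). Of those called in the first and last intervals, 3 were higher in both (2.15 for independent lists), 1 was lower in both (2.36), 7 were higher and then lower (2.75) and 9 lower and then higher (1.84). All intervals share 1 estimate of the spread of each gene, so a gene of low spread is more easily called in both. An overlap above that of independent lists can therefore arise in either direction and is not read as a shared change.

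Sex-linked genes were checked on each array. Xist, the RNA of the inactive X chromosome, had signals from 75.19 to 162.7 on the 15 epididymis arrays and 6047 in the newborn pool of both sexes. The Y-linked genes Eif2s3y, Kdm5d and Uty had signals of 1369 to 4520, 311.7 to 1694 and 274.9 to 614.2 on the epididymis arrays and 524.8, 216.9 and 123 in the pool.

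The newborn pool gives a reference for the organ, with 1 array and so no test. It also differs from the pnd2 samples in age, in sex and in its strain label, so a difference need not be particular to the organ. With gd18 in place of pnd2, 15 of the ratios of the genes named below moved by at least their pnd2 SD. At least 4-fold differences from the pool on each of the 3 pnd2 arrays were seen for 255 genes that were higher and 361 that were lower in the epididymis. Defb29 was 94.8-fold above the pool (6.57 on the log2 scale, pnd2 SD 0.61, n = 3 against 1), and Sult1e1, an estrogen sulfotransferase, was 50.5-fold above it. C1qtnf7, Foxl2os, Npy6r, the protease inhibitor genes Spink8 and Spink12, Map3k21 and Col4a6 were 35.2-, 33.2-, 28.4-, 27.7-, 21.8-, 27.1- and 25.5-fold above the pool. Emx2, a homeobox gene needed for the urogenital tract, was 23.5-fold above it, and Zfp979, Firre, Adgrg2, Pkhd1 and Aff3 were 19.6- to 22.4-fold above it. The liver genes Afp, Alb and Hpx were 1.04e+03-, 939- and 198-fold below the pool. The muscle genes Acta1, Ttn, Tnnt3 and Actn2 were 366-, 249-, 161- and 156-fold below it, with pnd2 SDs of 3.50, 3.48, 2.29 and 2.36 on the log2 scale. Skeletal muscle markers stood high on pnd2 replicate 2, and without it these genes were 1.45e+03-, 1e+03-, 365- and 399-fold below the pool and Hpx 344-fold. Without replicate 1 Acta1, Ttn and Actn2 were 230-, 131- and 91.8-fold below it. Without replicate 3 Acta1, Ttn, Tnnt3, Actn2 and Hpx were 147-, 118-, 74.7-, 103- and 114-fold below it, and Spink8 and Spink12 were 16.8- and 14.5-fold above it. Cpa1, the epidermal keratin gene Krt5 and Slc4a1 were 201-, 152- and 140-fold below it.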

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

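Of the tests in this part, that of the control ratios on pnd2 replicate 3 was chosen only after the result was seen. Groups of 3 arrays were not tested for outlying samples.

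The comparisons use probe sets with a single gene symbol, and 4368 kept probe sets have none. Of these, 875 (20%) changed over the 5 stages in a limma fit of every kept probe set, against 21.1% of the 21613 with 1 symbol. The 6 with the widest range between stage means were all highest at gd12, and the widest range was 6.54 on the log2 scale.

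In control probe sets, which the comparisons do not use, the 3' to 5' ratio of Gapdh on pnd2 replicate 3 was 63.16, against 4.333 to 7.18 on the other 14 epididymis arrays, and this array differed from its stage mates by at least 2-fold for 36.2% of genes. A gene-level difference of this animal would move the probe sets of a gene together, and across 5531 genes with at least 2 probe sets the deviations of the brightest 2 correlated only at r = 0.249. The same measure reached 0.571 to 0.679 for gd12 arrays set against the gd14 mean, but only 0.335, 0.352 and 0.27 for pnd2 replicates 1, 2 and 3 set against the gd18 mean, and 0.065 to 0.326 for the other arrays within their own stages, so it speaks only weakly against such a difference. Partly degraded RNA or short amplification products may account for the pattern, since either would raise the ratio as seen, and which of them it was, and whether the animal also differed, stays open.

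Other splits of the arrays were fitted in the same way. For gd14 against gd12, gd16 against gd14, gd18 against gd16 and pnd2 against gd18, the real counts were 1524, 13, 40 and 73 and the highest count of the other 9 splits of the 6 arrays was 0 in each. For pnd2 against gd12 the real count was 3362 and the highest other 5. These 10 splits are too few for a share under 0.05. Over the 5 stages, 1 of 100 splits, the real one, gave 3239 genes and the highest other gave 1303. Groups that mix stages take real stage differences into the spread, which lowers their counts. The splits therefore cannot exclude a grouping by chance for any of these counts.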

How the results depend on the processing

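The fit without the 3 arrays in doubt and the ratios to the newborn pool without single pnd2 arrays were chosen only after the result was seen. No paired analysis was possible because the stages share no replicate numbers.

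Leaving out each array in turn gave 938 (without gd12 replicate 14) to 3648 (without pnd2 replicate 3) genes for gd14 against gd12, and 3 (without gd14 replicate 10 or 11) to 142 for gd16 against gd14. It gave 6 to 214 for gd18 against gd16 and 3 to 240 for pnd2 against gd18, in both with the lowest value without gd18 replicate 6. It gave 2501 to 4365 for pnd2 against gd12 and 2330 to 5588 over the 5 stages, in both with the lowest value without gd12 replicate 14. The highest value came without pnd2 replicate 3 each time. Without all 3 arrays in doubt the count was 2776 for gd14 against gd12 and 33 for gd16 against gd14. Array quality weights, which gave pnd2 replicate 3 a weight of 0.046, led to 3480, 361, 354 and 413 genes in the consecutive intervals and 5495 over the 5 stages. Fits to the 6 arrays compared gave 3091, 281, 225 and 0 genes in these intervals and 1125 for pnd2 against gd12, and in the limma fit with 0 genes 950 had an unadjusted p under 0.05. In these fits the spread comes from fewer arrays, and pnd2 replicate 3 weighs on the last 2 of them alone.

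At an adjusted p under 0.01 the counts were 776, 3, 6 and 7 in the intervals, 1898 for pnd2 against gd12 and 1768 over the 5 stages, and with at least 2-fold they were 931 for gd14 against gd12 and 2025 for pnd2 against gd12. Both settings only narrow the call. Testing every probe set gave 145 for pnd2 against gd18, 5476 for pnd2 against gd12 and 5440 over the 5 stages, from more features tested. Quantile normalization gave 33 for gd16 against gd14 and 113 for pnd2 against gd18, and median centring 44 for the latter. A constant of 1 gave 8 for gd16 against gd14 and 24 for gd18 against gd16, and a constant of 64 gave 29 for gd16 against gd14 and 110 for pnd2 against gd18. For gd16 against gd14 the mean of the probe sets gave 23 and no trend gave 20. Avoiding probe sets that end in _x_at or _s_at gave 23 for gd18 against gd16, and no filter gave 41 for pnd2 against gd18. For these settings the cause was not tested.

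No named gene and no list that passed changed its sign under the settings run for it. Named genes were not run with array weights, without the 3 arrays in doubt or in the fits to 6 arrays. The larger direction among changed genes did turn: for gd14 against gd12 after median centring (651 higher, 695 lower), for pnd2 against gd18 after median centring (33 and 11), after quantile normalization (62 and 51) and without gd18 replicate 4 (7 and 6), and for pnd2 against gd12 with the mean of probe sets (1574 and 1759), with every probe set (2665 and 2811) and without pnd2 replicate 1 (1894 and 2052) or 2 (1836 and 2047). For gd16 against gd14 it turned without gd18 replicate 5 (3 and 4) and gd16 replicate 7 (2 and 3). The cause was not tested. The correlations between intervals moved by less than their limits under each alternative run. Of 145 list tests, 40 lost their call with an estimated correlation and at most 12 under any other setting. Of the 100 calls of named genes, 15 were lost with a constant of 1, 12 after median centring, 9 with the mean of probe sets, 7 with probe sets ending in _x_at or _s_at avoided, 1 after quantile normalization and 0 with a constant of 64, and 242 calls were lost over the 15 fits with 1 array left out. Of the 25 ratios to the newborn pool, 15 moved with gd18 in place of pnd2, 14 with a constant of 64, 6 with a constant of 1 and 4 after median centring. Leaving out pnd2 replicate 1, 2 or 3 moved 3, 5 or 7 of them by over 1.5 times. Signals far below 16 carry no order here, so levels near it limit the folds.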

Other observations

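The test of testis tissue on gd16 replicate 9 and the values of the extra gene lists without single gd12 arrays were chosen only after the result was seen, and the gene lists used here were written after the main comparisons.

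Genes that respond to low oxygen stood lower at pnd2 than at gd18. A list of 28 hypoxia-induced genes was drawn up without the genes already named, such as Ldha, Slc2a1, P4ha1 and Ak4, and 25 were measured. Of these, 23 had lower values at pnd2 (median log2 change -1.02, n = 3 arrays per stage), and Ankrd37 (-1.82 ± 0.25), Pgam1 (-1.02 ± 0.16) and Slc2a3, a glucose transporter (-0.97 ± 0.18), were called. The camera p of the list was 7.69e-14 and its p with an estimated correlation was 0.00486. With pnd2 replicate 3 left out the median was -0.945 and 12 genes were called lower, among them Aldoa, Pfkl, Pdk1 and Bnip3, and the p with an estimated correlation was 0.00392. From gd16 to gd18 the same list had a median of 0.31 (camera p = 3.15e-05, p = 0.0731 with an estimated correlation), and from gd12 to gd14 it had -0.05. A common fall of hypoxia-induced genes after birth may account for this pattern, as a hypothesis found and tested on the same arrays. The time from death to freezing of fetal and newborn organs was not tested and stays open.

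Germ cell and gonad genes were higher at gd12 than later, with Dazl at signals from 1216 to 2611 at gd12 and from 161.9 to 239.8 at gd14, and scaling of the arrays does not account for it, since the median log2 change of the germ cell list was -2.471 after quantile normalization. Gonad tissue in the gd12 samples could be a source, and of 7 early gonad genes outside the fixed lists 3 fell to gd14, Nr0b1 (-3.49 ± 0.50), Vnn1 (-2.74 ± 0.61) and Cyp26b1 (-2.05 ± 0.44), and 0 rose. Their median was -0.44, short of the limit of -0.5 set for gonad tissue, without gd12 replicate 13, 14 or 15 the median of all 9 measured genes of this list was -0.505, -0.494 or -0.571, and Zfpm2 and Runx1 had 0.71 ± 0.28 and 0.97 ± 0.33, so the list lies at the limit and does not decide. Sertoli cell genes (7 of 8 with lower values at gd14, median -2.05) add no separate weight, since the fixed testis list holds 7 of them, and lower values were also seen for 7 of 7 adrenal cortex genes (median -0.69, or 6 of 7 without gd12 replicate 13 or 15), with Nr0b1 in both the gonad and the cortex list. At gd12 the Sertoli cell genes Dhh, Aard, Cst9 and Dmrt1 had signals of 932.5 to 3161, 2422 to 6127, 795.4 to 3107 and 360.3 to 1027. Sox9 had 873.7 to 1455, while Amh, Fshr and Mro reached only 32.8, 100.5 and 116.9. For the germ cell and Sertoli cell genes that stood high together, these signals argue against a change within the duct and mesonephros as the only source. The test set for gonad tissue did not decide it. For the other genes gonad tissue and a change with age cannot be told apart here. Organs were excised whole, and 1 stage differs from the next in both.

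Steroidogenic genes stood high on gd16 replicate 9, with signals of 2211 for Cyp17a1, 598 for Star, 549.3 for Hsd3b1 and 510.8 for Cyp11a1, against 136.4 and 140.3 for Star and under 60 for the others on the remaining gd16 arrays. Testis tissue in the sample could bring these genes, and 8 Sertoli cell genes, 7 of which the testis list also holds, had a median log2 deviation of 0.42 on this array (SE of the mean 0.44, 6 of 8 higher), with Cst9 at 185.7 against 4.75 and 28.62, Fshr at 113.8 against 3.19 and 15.04, Mro at 76.67 against 19.18 and 23.43, Sox9 at 147.5 against 163.8 and 209.8, and Amh near background on every array (3.92 to 38.35). The fixed testis list, which holds steroidogenic genes too, had 0.82 (12 of 13 higher), and the germ cell list had 0.31 (7 of 10 higher), less than the 0.61 (7 of 10 higher) on gd16 replicate 7, while single germ cell genes, chosen after their values were seen, stood out, Mael at 142.5 against 1.74 and 5.45, Ddx4 at 87.48 against 4.11 and 17.98 and Sall4 at 76.13 against 8.37 and 4.95. Adrenal cortex tissue could bring them too, and 7 adrenal cortex genes had a median of 0.82 (SE of the mean 0.25, 6 of 7 higher), with Cyp11b1 at 195.2 against 55.95 and 34.71 and Cyp21a1 at 56.38 against 81.2 and 54.16. In the adrenal list Scarb1 was at 2056 against 747.5 and 977.1, and Cyp11b2 at 61.11 against 55.3 and 46.42. The median of that list was the deviation of Mrap, a dim gene here, at 29.87 against 7.29 and 12.99, and at 1154 in the newborn pool. Of the early gonad genes Vnn1 was at 979.4 against 181.2 and 122.2, while that list had a median of 0.098. With 1 array and deviations of this spread neither testis nor adrenal cortex tissue can be excluded, and which of them it was stays open.

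On gd12 replicate 14 the adrenal chromaffin genes Chgb (chromogranin B), Ddc, Th and Chga had signals of 2525, 889.4, 404.9 and 328, against 94.07 and 142.7, 338.5 and 351.6, 92.19 and 112.6, and 11.32 and 62.56 on the other gd12 arrays, while Dbh had 320 against 163.4 and 34.96 and Pnmt 287.1 against 97.61 and 485.1. All 6 genes of this list had lower values at gd14 than at gd12 (median log2 change -1.02), without this array 5 of 6 did (median -0.32), and their median deviation on gd16 replicate 9 was 0.15. On pnd2 replicate 2 Ttn (titin) had a signal of 1537, against 10.64 and 5.48 on the other pnd2 arrays.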
